A study of Bos indicus with 8 samples.

How the data were processed

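Gene expression was measured in blastocysts of Bos indicus that had been vitrified and warmed with the Cryotop, a thin film strip on which embryos are cooled in a very small volume, and in control blastocysts that were not cooled. Per the labels, the embryos were produced in vitro, graded between 144 and 156 h after insemination, vitrified in 15% ethylene glycol, 15% dimethylsulfoxide and 0.5 M sucrose, held in liquid nitrogen for at least 30 min, warmed through 1 M and 0.5 M sucrose and cultured for 4 h more, as the controls were. Each pool held 10 embryos per the labels. RNA was amplified before labelling, and each of 8 two-colour arrays carried 1 vitrified and 1 control pool. The vitrified pool was in Cy5 (red) on areas 1 and 3 of each of 2 slides, the first and the second slide below, and in Cy3 (green) on areas 2 and 4.

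The deposited scanner files give, per the file headers, the intensity of each spot and of its local background in both channels, neither background-corrected nor normalized. The scanning software is not given in the sources used here. The authors' deposited value table holds 1 normalized log2 value per probe and array. Its scale and direction were found by setting each column against the scanner values: it correlated with the normalized ratio at r of 0.68 to 0.83 across probes, which are not independent replicates, with slopes of 0.94 to 1.31, so the table was read as log2 of vitrified over control. Its column medians were 0.0031, -0.0012, -0.00032 and 0.0035 on areas 1 to 4 of the first slide and -0.0098, 0.00064, -0.010 and 0.010 on the second slide. The authors' normalization method stays unknown, and the table served as an alternative.

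Each array had 45212 named spots, of which 43794 were gene probes and 1418 were controls. Another 8 spots without a name and the 14 summary lines of each file were left out. The mean spot intensities were background-corrected with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. A spot counted as above background when its log2 signal exceeded the mean plus 2 SD of the 153 negative control spots in its channel. A probe was tested when it was above background on at least 4 of the 8 arrays in the vitrified or in the control channel, which left 34912 probes. The platform annotation gave 1 gene symbol to 21790 probes, several to 0 probes and none to 22004, which are unnamed here. It can be old: 12516 of its 15229 distinct symbols were found in the RefSeq gene table of the assembly NIAB-ARS_B.indTharparkar_mat_pri_1.0, which was used for names and chromosome assignment, with no coordinates. The tested probes covered 13136 named genes, 3235 of them by more than 1 probe.

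The labels give each array a biological replicate number from 1 to 4, and each number stands on 1 array of each slide in the same dye orientation. As fixed before the data were examined, the 2 arrays of a number were averaged, and limma's lmFit and eBayes fitted a vitrification term and a dye term per probe to the 4 averages. A probe was called at a Benjamini-Hochberg adjusted p under 0.05. The series' design text describes a dye swap, which arrays of a shared number do not form. Arrays on neighbouring areas (1 and 2, 3 and 4) of a slide deviated together as dye swaps of the same pools would, so that the replicate numbers appeared to split such pairs. If so, the fit by replicate numbers counts pools more than once and its p-values are too small. Another fit written down in advance, in which each neighbouring pair is averaged after turning the sign and the 4 pair means are tested against 0 with limma, is therefore given beside it. The log2 ratio of a probe is the same in both fits, and its SD is given over the 4 dye-swap pairs. The labels call the replicates biological, and nothing else was given on whether the pools came from separate cultures. Over dye-swap pairs, the p-values of single probes therefore measure only the spread between these pools. By replicate numbers, each average mixes pools of both slides if neighbouring areas share pools, and the spread between slides is left out. XIST, a gene named below with pairs from -1.55 to -0.15, had a limma p of 1.5e-05 by replicate numbers and 0.019 over pairs. The list test below, at a preset correlation, sets the genes of a list against the other genes. Its p-values do not measure the spread between pools.

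Named genes followed a rule fixed in advance. Called genes with the same sign in all 4 replicates came first, the 12 largest in each direction. Where fewer passed, the genes with the smallest unadjusted p in the fit by replicate numbers filled up the 12, among those with an absolute log2 ratio of at least 0.58 and the same sign on all 8 arrays, with 1 probe per symbol, and they are given as values that did not pass. For each of 27 fixed gene lists, members that passed were to be named, and otherwise the 2 with the smallest p, taken from the fit with 1 probe per gene that the list test used. Lists were tested with camera in limma at a preset correlation between genes of 0.01, two-sided, with the probe of highest mean intensity for each gene, and adjusted over the 26 lists with at least 5 measured members. Alternatives were camera with an estimated correlation and fry. With an estimated correlation, camera takes its degrees of freedom from the 4 averages and not from the genes, so it can call only very large shifts. A list's median was also placed among 10000 random lists matched on mean intensity.

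The fits were tested on simulated data for the vitrified over control comparison over 34912 probes, with 200 probes changed by each of 3 sizes, variances and their intensity trend taken from the arrays, and arrays built as dye-swap pairs. At log2 changes of 0.5, 1 and 2 the fit over dye-swap pairs called 119, 183 and 195 of the 200, with 22 false calls, and 5.35% of unchanged probes had an unadjusted p under 0.05. The fit by replicate numbers called 111, 178 and 194 with 48 false calls, and that share was 8.92%. Taking 8 arrays as independent called 155, 195 and 199 with 96 false calls and a share of 9.36%. The way variances were simulated was revised 2 times after the output of the simulation had been seen, and these figures are those of the last version. They hold only for its variances, for its number and sizes of changed probes and for probes drawn independently of each other. On the arrays 14 of 34912 probes had an absolute log2 ratio over 1. The recovered counts therefore do not give the share of real changes that would be called. Alternatives covered background correction, normalization, the filter on dim probes, the dye term, the treatment of arrays and slides, each replicate number and each pair left out, the variance model, array weights, the deposited values and the spot statistic. With arrays, their number limits the precision.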

Results

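Whole-genome expression of vitrified and warmed blastocysts was compared with that of control blastocysts on 8 two-colour arrays, each carrying 1 pool of vitrified and 1 pool of control embryos, on 2 slides. The arrays formed 4 neighbouring pairs in which the dyes were swapped. Median probe intensity ranged from 106.5 to 153.2 in Cy5 and from 149.1 to 243.3 in Cy3. Between 72.3% and 79.2% of probes were above background on 7 arrays, and 28.0% on the second slide area 1.

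The comparison asks which transcripts differ in embryos that were vitrified, warmed and cultured for 4 h. No gene passed the test, so the genes below are values. Among the transcripts with the same sign on all 8 arrays, the higher values in vitrified embryos included HSPA5, the main chaperone of the endoplasmic reticulum, at a log2 ratio of 0.85 ± 0.43 (SD, n = 4 dye-swap pairs), SEC24D, a coat protein of transport vesicles, at 0.91 ± 0.32, MANF, a secreted stress-induced factor, at 0.62 ± 0.23, and DNAJB9, a co-chaperone, at 0.59 ± 0.23. GADD45B, a stress-inducible growth arrest gene, was at 1.03 ± 0.29, which is 2.04-fold, and FOSL1, a subunit of the AP-1 transcription factor, at 0.80 ± 0.29. Lower values included SLC1A4, a neutral amino acid transporter, at -1.18 ± 0.49, PSAT1, an enzyme of serine synthesis, at -0.83 ± 0.39, XIST, the RNA that silences 1 X chromosome in female cells, at -0.88 ± 0.63, and PDGFRA, a receptor found in primitive endoderm, at -0.86 ± 0.43.

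Of the other genes of the rule, UPK1A, a uroplakin, was at 1.02 ± 0.60 and XBPP1, as the annotation lists it, at 0.74 ± 0.41. SPTY2D1 was at 0.74 ± 0.33, CRAT, carnitine acetyltransferase, at 0.71 ± 0.42, BTBD1 at 0.66 ± 0.24 and NDFIP2 at 0.59 ± 0.37. On the lower side, TKTL2 was at -0.71 ± 0.12, NOP10 at -0.65 ± 0.40, DCK, deoxycytidine kinase, at -0.64 ± 0.45, GFRA1 at -0.61 ± 0.14, TIAL1, an RNA-binding protein, at -0.60 ± 0.12, DBT at -0.60 ± 0.38, LOC510631 at -0.60 ± 0.31 and HS3ST5 at -0.58 ± 0.33. Probes of one gene disagreed for several of these: the other probes of SLC1A4 were at -1.32 and 0.02, those of PDGFRA between -0.31 and 0.06, those of TIAL1 between -0.15 and 0.07, that of NOP10 at 0.07 and that of HS3ST5 at 0.01. The other probes of DCK lay between -0.39 and -0.30 and those of NDFIP2 between 0.19 and 0.25. GFRA1 and LOC510631 had the lowest mean log2 intensities of the named genes, 7.67 and 7.90. Each was above background on 7 arrays in the vitrified and 7 in the control channel, so their ratios rest on low signal.

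With limma by replicate numbers, 0 of 34912 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.109. At an unadjusted p under 0.05 there were 5174 probes, 2302 higher and 2872 lower. In simulated dye-swap pairs this fit put 8.92% of unchanged probes under that p. Simulated probes were drawn independently of each other, so that share need not hold for the arrays. With the replicate numbers split otherwise, the arrays themselves gave up to 4526 such probes. Over dye-swap pairs, limma called 0 probes, with a smallest adjusted p of 0.464 and 2688 probes at an unadjusted p under 0.05. The named genes had adjusted p between 0.109 and 0.112 by replicate numbers and between 0.464 and 0.557 over pairs. Fits that count the 8 arrays singly called 597 probes as independent arrays and 1043 with the replicate number as a block. If neighbouring areas hold the same pools, these fits count each pair of pools as 2 arrays. The correlation between arrays of 1 replicate number was estimated at -0.112. Being negative, it did not widen the errors of the block fit for repeated arrays. With slide as a fixed block the 8 arrays gave 365 calls and the dye-swap pairs 0, and each slide alone gave 0.

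**Figure D1:**
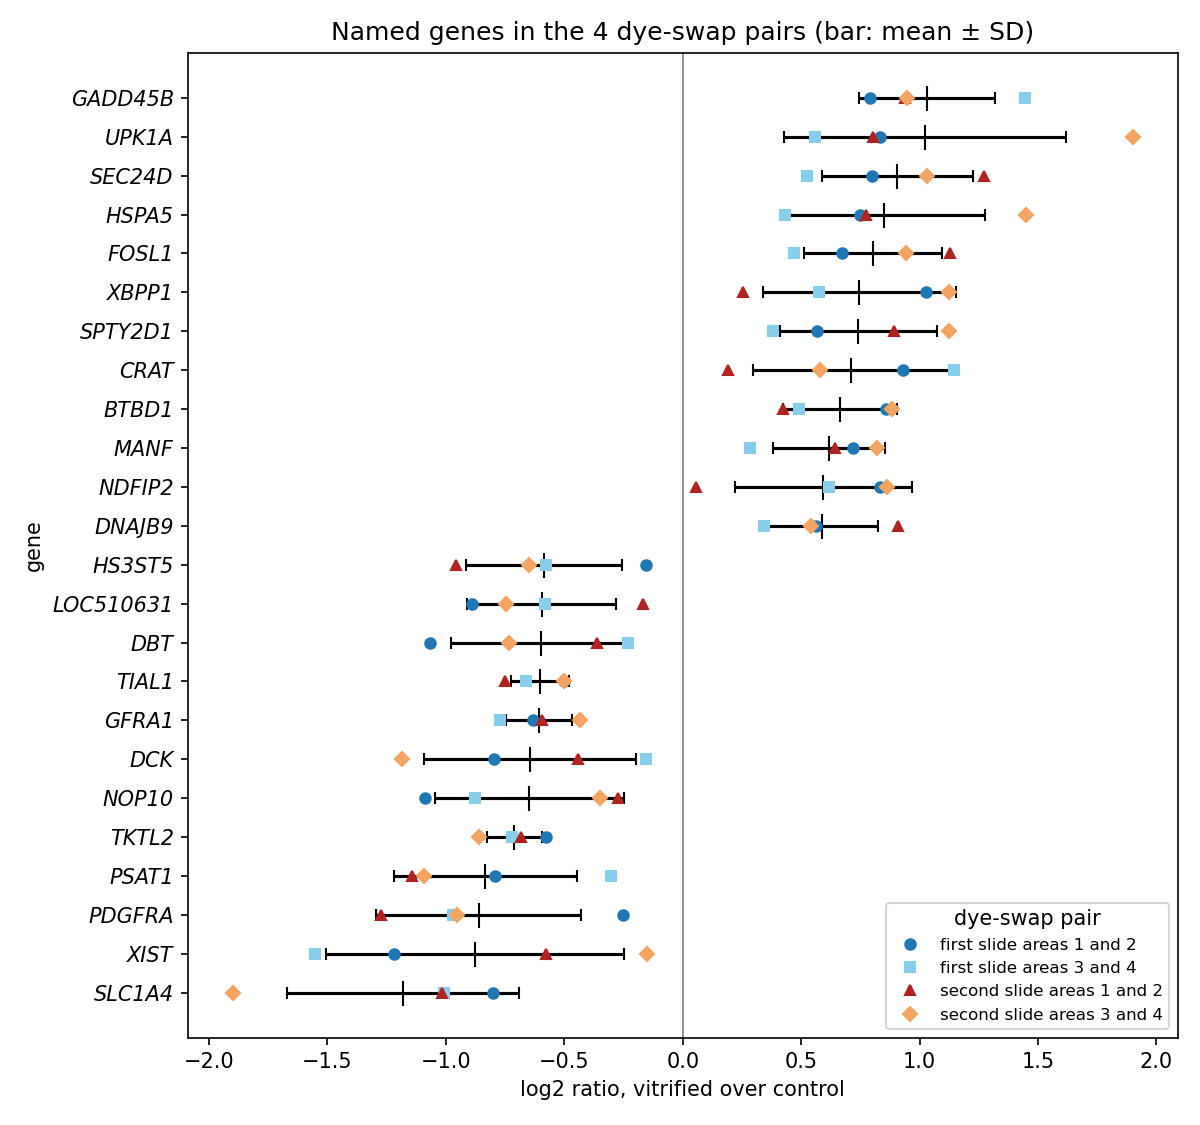
Log2 ratio of vitrified over control (horizontal axis) of the 24 named genes (vertical axis) in each of the 4 dye-swap pairs, with bars for mean and SD. Every pair lies on the same side of 0 for each gene, because the naming rule required the same sign on all 8 arrays, and XIST spreads from -1.55 to -0.15.

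Of the fixed gene lists, 5 shifted at the preset correlation of camera, and none of them held with an estimated correlation or with fry. By replicate numbers the estimated correlation was 0.0024 for ribosomal genes and 0.016 for the p53 list. It was 0.093 for trophectoderm markers, 0.15 for actin and keratin genes and 0.16 for pluripotency markers. For ribosomal genes it lay below the preset 0.01, so the loss of that call does not come from a higher correlation. For the other called lists the estimate lay above the preset, least so for the p53 list. If these estimates hold, the p-values of those lists at the preset correlation are too small. Trophectoderm markers were higher, with 22 of 26 members above 0 and a median log2 ratio of 0.20 (adjusted p = 0.00018 by replicate numbers and 0.00025 over pairs, adjusted p = 0.747 with an estimated correlation). IFNT, the interferon of pregnancy recognition and a multigene family whose copies one probe may not separate, was at 0.80 ± 0.52, and EFNA1 at 0.47 ± 0.16, both picked after their values were seen. The list's median was 0.426 with probes above background in all channels, 0.124 without replicate 4 and 0.124 with the mean over the probes of a gene, and it was called in each. By the rule, GATA2 was at 0.43 ± 0.33 and DAB2 at 0.26 ± 0.17. Pluripotency markers were lower, with 17 of 19 below 0 and a median of -0.12 (adjusted p = 0.00071 and 0.0013, adjusted p = 0.848 with an estimated correlation). NANOG, a core pluripotency factor, was at -0.49 ± 0.25 and TDGF1 at -0.33 ± 0.24, whereas POU5F1, picked after its value was seen, was at 0.08 ± 0.09. With probes above background in all channels the list was not called (median -0.086, adjusted p = 0.153).

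Cytosolic ribosomal protein genes were higher in 26 of 30, with a median of 0.08 (adjusted p = 0.00064 and 0.00025, adjusted p = 0.747 with an estimated correlation), and RPL14 was at 0.20 ± 0.14 and RPLP1 at 0.18 ± 0.12. Such genes have many copies in the genome that can share probe signal. The p53 and DNA damage list was higher in 13 of 18, with a median of 0.13 (adjusted p = 0.0048 and 0.0020, adjusted p = 0.747 with an estimated correlation), and GADD45A was at 0.24 ± 0.22 and TP53I3 at 0.19 ± 0.20. With probes above background in all channels the p53 list was not called (median 0.153, adjusted p = 0.0955), and without replicate 3 its median was 0.085 (adjusted p = 0.0082). Actin cytoskeleton and keratin genes were higher in 21 of 30, with a median of 0.11 (adjusted p = 0.0055 and 0.0085, adjusted p = 0.867 with an estimated correlation), and MYL6 was at 0.26 ± 0.32 and RDX at -0.33 ± 0.19. The other probes of RDX were at 0.01 and 0.02. The smallest adjusted p of fry over all lists was 0.128 by replicate numbers and 0.568 over pairs. KRT8, KRT18 and KRT19 stand in both the keratin and the trophectoderm list. With median centring in place of loess, the p53 median was 0.103, against 0.134, and the list was not called (adjusted p = 0.068). The medians of the actin and ribosomal lists were then 0.028 and 0.0030 (adjusted p = 0.347 and 0.589). Without the pair on the second slide areas 3 and 4, the trophectoderm median was 0.119 (adjusted p = 0.0210) and the pluripotency median -0.040 (adjusted p = 0.067). Without the first slide areas 3 and 4, the actin median was 0.051 (adjusted p = 0.319) and the p53 median 0.113 (adjusted p = 0.0921). Without the first slide areas 1 and 2, the actin median was 0.094 (adjusted p = 0.0925) and the ribosomal median 0.044 (adjusted p = 0.010). Without the second slide areas 1 and 2 the ribosomal median was 0.123 (adjusted p = 5.3e-05), and without the first slide areas 3 and 4 the pluripotency median was -0.178 (adjusted p = 0.0028). The actin list was not called without replicate 4 (median 0.085, adjusted p = 0.0527), nor the ribosomal list with the deposited values (median 0.070, adjusted p = 0.0868 by replicate numbers and 0.101 over pairs).

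Whether the slides differed was not tested. If neighbouring areas hold the same pools, the fit of each slide alone counts each pair of pools as 2 arrays. On the first slide alone the median of trophectoderm markers was 0.29 (adjusted p = 3.5e-06), and on the second slide alone it was 0.20 (adjusted p = 0.127). Pluripotency markers were at -0.11 (adjusted p = 0.0136) and -0.18 (adjusted p = 0.0708), ribosomal protein genes at 0.14 (adjusted p = 0.00019) and 0.03 (adjusted p = 0.497), the p53 list at 0.14 (adjusted p = 0.00081) and 0.05 (adjusted p = 0.497), and actin and keratin genes at 0.27 (adjusted p = 3.5e-06) and 0.02 (adjusted p = 0.962). With slide as a block over dye-swap pairs, limma's camera at the preset correlation gave adjusted p of 0.00020 for trophectoderm markers and ribosomal protein genes, 0.0015 for pluripotency markers and the p53 list, and 0.0053 for actin and keratin genes. With an estimated correlation over pairs, without the block, none was called (adjusted p = 0.850 for the first 4 and 0.908 for actin and keratin genes). By slide this correlation was not estimated. In the pair on the second slide areas 1 and 2, the trophectoderm median was -0.06, the pluripotency median 0.04 and the actin and keratin median -0.06, opposite to the other pairs. With the spots left out whose local background exceeded their signal, they were -0.10, 0.03 and -0.07.

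Endoplasmic reticulum stress genes had 15 of 22 members above 0 and a median of 0.15 (adjusted p = 0.0628 and 0.0579, adjusted p = 0.747 with an estimated correlation), so it was not called. Adjusted over the list alone, 9 of its members passed by replicate numbers and 6 over pairs, among them HSPA5 and DNAJB9 with ratios above 0 and ATF4 at -0.34 ± 0.06 and ASNS at -0.48 ± 0.25, which act in the amino acid response. ATF4 was picked after its value was seen. Over all probes tested 0 members of any list passed. Adjusted over the list alone, immediate early genes had 9 by replicate numbers and 2 over pairs (GADD45B and FOSL1), trophectoderm markers 8 and 1, primitive endoderm markers 6 and 2, oxidative stress genes 4 and 0, cell cycle genes 3 and 0, pluripotency markers 2 and 0 and proteasome genes 2 and 0. Heat shock, apoptosis, p53, epithelial junction, histone, cumulus and oocyte lists each had 1 by replicate numbers and 0 over pairs, and sperm markers had 1 and 2. The other lists had 0 in both.

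Lists for other stress types were not called. Heat shock proteins had a median of -0.0050 (adjusted p = 0.749), with HSPB8 at 0.34 ± 0.35 and BAG3 at 0.17 ± 0.28. Cold response genes were at 0.08 (adjusted p = 0.598), with CDKN1A at 0.17 ± 0.20 and CIRBP at 0.24 ± 0.47. Osmotic stress and aquaporin genes were at -0.01 (adjusted p = 0.749), with SLC38A2 at -0.36 ± 0.19 and SLC12A2 at -0.16 ± 0.07. Immediate early genes were at 0.02 (adjusted p = 0.291), oxidative stress defence genes at 0.01 (adjusted p = 0.608), with GPX4 at 0.30 ± 0.24 and GSTP1 at 0.35 ± 0.27, and apoptosis genes at -0.0042 (adjusted p = 0.608), with CASP8 at -0.49 ± 0.54 and CASP9 at -0.36 ± 0.50. In the fit over all probes DIABLO, at -0.14 ± 0.08, came second in place of CASP9. The other probes of CASP9 were at 0.11 and 0.13. CASP8 had a mean log2 intensity of 7.47 and was above background on 4 arrays in the vitrified and 7 in the control channel. Inflammatory genes were at 0.01 (adjusted p = 0.749), with NFKB2 at 0.16 ± 0.08 and IRF1 at -0.05 ± 0.21.

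Of the lists for metabolism and cell structure, sterol synthesis genes had a median of 0.10 (adjusted p = 0.480), with MVK at 0.23 ± 0.25 and TM7SF2 at 0.15 ± 0.08. Glycolysis genes were at -0.01 (adjusted p = 0.749), with SLC2A1 at -0.20 ± 0.12 and SLC2A8 at 0.26 ± 0.14, oxidative phosphorylation genes at 0.02 (adjusted p = 0.678), with SDHA at 0.26 ± 0.19 and UQCRC2 at -0.16 ± 0.22, and lipid genes at -0.01 (adjusted p = 0.749), with FADS2 at 0.22 ± 0.49 and ACADM at -0.21 ± 0.15. Epithelial junction genes were at -0.0041 (adjusted p = 0.749), with GJA1 at -0.48 ± 0.58 and CLDN4 at 0.18 ± 0.25. Primitive endoderm markers were at -0.06 (adjusted p = 0.749), with PDGFRA as above and LAMA1 at 0.31 ± 0.22. Chromatin and imprinted genes were at -0.01 (adjusted p = 0.749), with HDAC2 at -0.21 ± 0.21 and UHRF1 at 0.28 ± 0.32, cell cycle genes at -0.03 (adjusted p = 0.598), with RRM2 at 0.40 ± 0.35 and MCM6 at -0.32 ± 0.19. The 3 other probes of RRM2 lay between -0.04 and -0.02. Proteasome genes were at -0.02 (adjusted p = 0.749), with PSMA3 at -0.24 ± 0.18 and PSMD12 at 0.24 ± 0.19, and histones at 0.00081 (adjusted p = 0.835), with SLBP at -0.33 ± 0.15 and HIST3H2A at 0.34 ± 0.24, or H2AFY, at 0.10 ± 0.18, as the second by the fit over all probes. Markers of other cell types were not called. Cumulus markers were at -0.02 (adjusted p = 0.608), with LUM at -0.60 ± 1.30 and INHBB at -0.09 ± 0.07. Oocyte markers were at 0.03 (adjusted p = 0.621), with ZP4 at -0.26 ± 0.18 and FIGLA at 0.13 ± 0.14, and sperm markers at 0.02 (adjusted p = 0.749), with SPAM1 at 0.38 ± 0.17 and TNP1 at -0.19 ± 0.05. Mitochondrial genome transcripts had 0 measured members. The test pointed up for the heat shock and lipid lists, whose medians were below 0 and means above it, and down for histones, whose median and mean were above 0, and for the proteasome and chromatin lists, whose means were above 0.

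**Figure D2:**
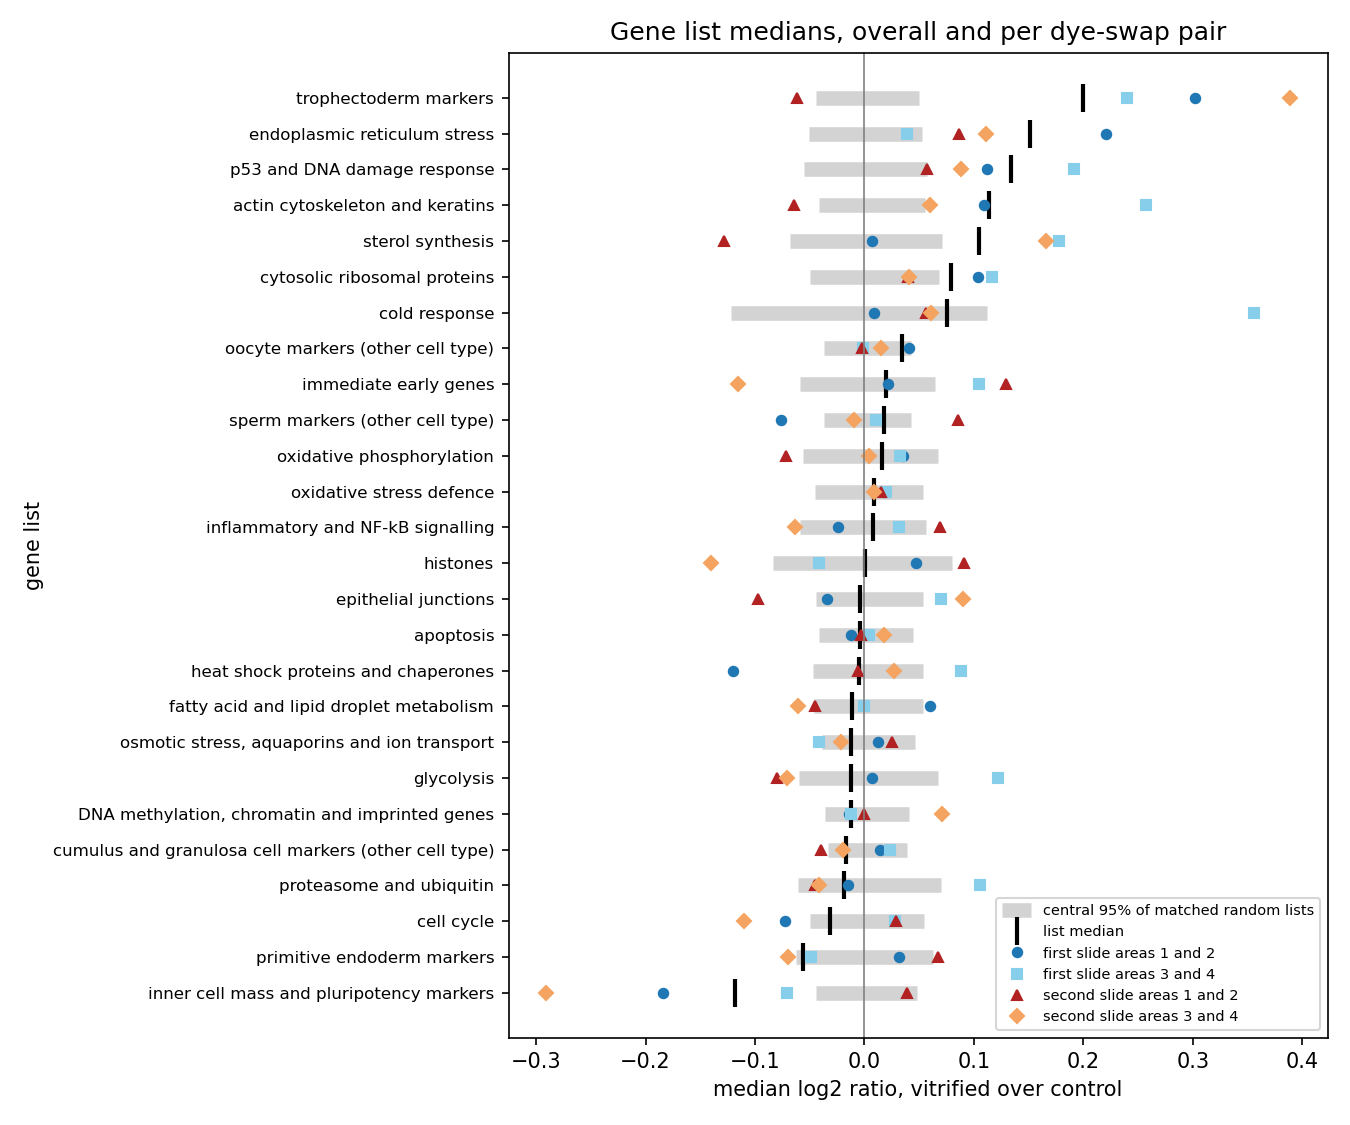
Median log2 ratio of vitrified over control (horizontal axis) of each tested gene list (vertical axis), overall (black bar) and in each dye-swap pair (symbols), with the central 95% of random lists matched on intensity in grey. The trophectoderm median of 0.20 lies outside the grey range, and the pair on the second slide areas 1 and 2 lies at -0.06.

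The arrays were compared with each other to see how repeatable the ratios were. Across probes, which are not independent replicates, the ratio of vitrified over control correlated at a mean r of 0.450 between arrays of the same replicate number and 0.411 between other arrays of the same dye orientation. It was -0.327 between arrays of opposite orientation that were not neighbours, and 0.113 between neighbouring areas. With the dye effect removed, the mean r was 0.834 between neighbouring areas, 0.0986 between arrays of the same number, 0.0218 between others of the same orientation and 0.0999 between others of opposite orientation. Once the vitrification and dye terms were removed, a step added after the data were seen, as was setting neighbouring areas apart, neighbouring areas had a mean residual r of -0.763. Arrays of the same number were at -0.261 and other arrays of the same orientation at -0.365. Removing the terms makes the residuals of the 4 arrays of an orientation sum to 0, so unrelated arrays of one orientation also have a negative r. Between the 4 dye-swap pairs the mean r was 0.0826. The same sign occurred in all 4 pairs for 15.9% of probes, where chance gives 12.5%. The dye term was called for 2610 probes, 692 brighter in red and 1918 brighter in green.

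**Figure D3:**
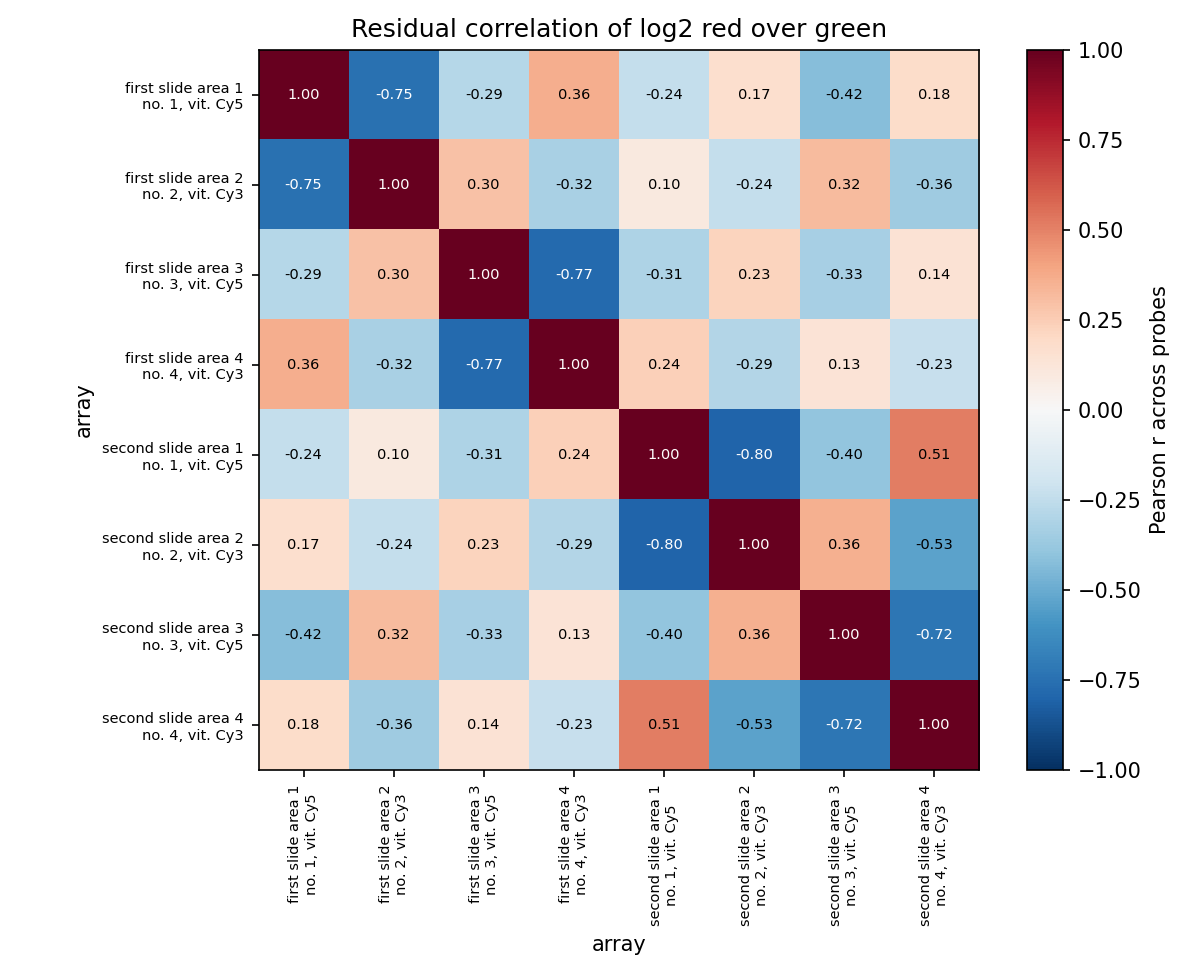
Pearson r across probes of the residual log2 red over green ratio between the 8 arrays, labelled by slide, area, replicate number and the dye of the vitrified pool. Neighbouring areas lie between -0.80 and -0.72.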

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

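The tests of Y-linked genes, of the whole inner cell mass, of X-linked genes with camera and of residuals between neighbouring areas were chosen only after the result was seen, and the others before. Of 55 groups of values, 3 held a value far from the others, where chance gives about 2.75. On the second slide area 1, 28.0% of probes were above background, against 72.3% to 79.2% on the other arrays, and with outlying negative control spots left out of the limit the share was 75.8%. The median of the cold response list was 0.36 in the pair on the first slide areas 3 and 4, against 0.01 to 0.06 in the others. The median of the chromatin and imprinted gene list was 0.071 in the pair on the second slide areas 3 and 4, against -0.014 to -0.00050 in the others.

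Arrays that share a replicate number correlated at a mean r of 0.450, against 0.411 for other arrays of the same dye orientation, and their residual r was -0.261, against -0.365, where removing the terms makes the mean r within one orientation negative. If neighbouring areas held the same pools with the dyes swapped, their residual ratios would oppose each other, and their mean residual r was -0.763. A position artefact shared by neighbours would give a positive r, and the most positive of the 4 was -0.722, which argues against it. The same pools on neighbouring areas may therefore account for the pattern. Whether the labels' numbers mark something else was not tested.

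XIST was lower in all 4 pairs, from -1.55 to -0.15. A lower share of female embryos could lower X-linked genes too: on the first slide the X-linked minus autosomal median, over 373 X-linked genes, was -0.096 in one pair, below the range of random autosomal lists, and -0.012 in the other, within it. On the second slide it was -0.052, below the range, and 0.017, within it. Over all arrays, camera gave the X-linked genes a p of 0.00049 by replicate numbers and 0.00067 over pairs at the preset correlation, and 0.266 by replicate numbers with an estimated one. More male embryos would raise Y-linked genes, with a bound of 0.1 set for the first slide. The means of DDX3Y, EIF1AY, ZFY and SRY were 0.088 and 0.054 there and 0.064 and 0.042 on the second slide. The mean log2 intensities of these genes were low, from 6.82 for ZFY to 7.77 for DDX3Y, against 10.55 for XIST. ZFY was above background on 3 arrays in the vitrified and 5 in the control channel. A bound on ratios this near background can hardly decide the question. The sex ratio of the pools and an effect of vitrification on XIST cannot be told apart, since the bounds were set for both pairs of the first slide, neither was met in both, and the embryos' sex is not given.

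Trophectoderm markers were higher and pluripotency markers lower at the preset correlation, and neither was called with an estimated one (adjusted p = 0.747 and 0.848) or with fry (adjusted p = 0.169 and 0.205). If signal intensity alone were the cause, both medians would lie within the range of random lists matched on intensity. The trophectoderm median was at percentile 100.0 and the pluripotency median at percentile 0.010 of such lists, which argues against intensity alone as the cause. Genes of the random lists were drawn independently, so their range can be too narrow for genes that vary together. Lists that were not called lay outside it too, among them endoplasmic reticulum stress at percentile 100.0 and sterol synthesis at 99.81. A loss of the whole inner cell mass would lower primitive endoderm markers as well. Their median of -0.056 lay within the random range, at percentile 3.7, so this stays open. DAB2, at 0.26, stands in both the trophectoderm and the primitive endoderm list. The difference between the list medians was 0.318, and the highest of the other sign splits of the pairs gave 0.287; 8 splits, the real one among them, are too few for a share under 0.05. Cell numbers per lineage were not analysed here.

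At an unadjusted p under 0.05 there were 2688 probes over dye-swap pairs, and the highest of the other sign splits gave 2735. By replicate numbers there were 5174, and the highest of the other balanced splits gave 4526. With 8 and 3 splits, the real one among them, both are too few for a share under 0.05.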

How the results depend on the processing

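The settings that leave out artefact spots, use median spot intensity, leave out a dye-swap pair or combine pairs with the deposited values, a slide block or another list test were chosen after seeing the data. The artefact spots are those with local background above signal: 5 on the second slide area 1 and 2 on the first slide area 4. The SD of normexp's fitted background in Cy5 was 293 and 54.2 on these arrays, and 4.93 and 3.62 without the 7 probes, and the SD of the log2 ratios went from 0.195 to 0.303 and from 0.263 to 0.295. The count of called probes stayed at 0 in 25 of 30 other settings. It was 1043 when the 8 arrays carried the replicate number as a block, 597 when they were taken as independent and 365 with slide as a fixed block and the replicate number as a random block; if neighbouring areas hold the same pools, each of these counts a pool pair as 2 arrays, and over pairs the count was 0. The deposited values gave 13 by replicate numbers, among them SPTY2D1, GADD45B, UPK1A, XIST, PDGFRA and SLC1A4, and 0 over pairs; the cause was not tested. An unadjusted p under 0.05 with at least 1.5-fold gave 134, a looser threshold. The 24 named genes kept their sign in every setting that measured them; they were chosen for the same sign on all 8 arrays, so settings that leave out or regroup arrays could not turn it.

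The number of called lists fell from 5 to 2 with median centring, to 0 on the second slide alone, and to 0 with an estimated correlation and with fry, each by replicate numbers and over pairs. Adjusted p with an estimated correlation was 0.747 (p53, trophectoderm, ribosomal), 0.848 (pluripotency) and 0.867 (actin) by replicate numbers, and 0.850 (p53, trophectoderm, pluripotency, ribosomal) and 0.908 (actin) over pairs. With fry it was 0.128 (p53), 0.169 (trophectoderm, ribosomal), 0.205 (pluripotency) and 0.235 (actin) by replicate numbers, and 0.568 (p53, trophectoderm, ribosomal), 0.673 (pluripotency) and 0.701 (actin) over pairs. Median centring gave 0.068 (p53, median 0.103 from 0.134), 0.347 (actin, 0.028 from 0.114) and 0.589 (ribosomal, 0.0030 from 0.079). Probes above background in all channels gave 0.0955 (p53, median 0.153) and 0.153 (pluripotency, median -0.086), with fewer genes tested. The second slide alone gave 0.127 (trophectoderm), 0.0708 (pluripotency), 0.497 (p53, ribosomal) and 0.962 (actin), whereas the first slide alone, with as many arrays, called 5 lists. Each slide alone counts a pool pair as 2 arrays if neighbouring areas share pools. The deposited values gave 0.0868 (ribosomal) by replicate numbers and 0.101 over pairs. Leaving out a pair gave 0.0011 to 0.0921 (p53), 0.00017 to 0.067 (pluripotency) and 5.3e-05 to 0.319 (actin), and leaving out a replicate number gave values within these ranges. If neighbouring areas hold the same pools, leaving out a replicate number takes no pool out of the fit. The p53 call was lost without the pair on the first slide areas 3 and 4 (0.0921, median 0.113), the pluripotency call without the second slide areas 3 and 4 (0.067, median -0.040 from -0.119), and the actin call without replicate 4 (0.0527), the first slide areas 1 and 2 (0.0925) or areas 3 and 4 (0.319, median 0.051 from 0.114). The causes were not tested.

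Some lists not called by replicate numbers changed direction in some settings, with the cause not tested. Their adjusted p was 0.914 (osmotic, oxidative stress), 0.533 (oxidative phosphorylation) and 0.857 (lipid) with median centring, 0.969 (sperm) without the filter, 0.739 (heat shock, epithelial junctions) with probes above background in all channels, and 0.982 (chromatin) with the mean over probes. On the first slide alone it was 0.674 (heat shock), 0.641 (epithelial junctions), 0.493 (glycolysis), 0.606 (proteasome) and 0.975 (cumulus), and on the second slide alone 0.962 (oxidative phosphorylation, histones), 0.497 (lipid) and 0.927 (chromatin). The deposited values gave 0.918 (oxidative phosphorylation), 0.933 (proteasome) and 0.866 (histones), and over pairs 0.980 (oxidative phosphorylation, lipid) and 0.900 (histones). Median spot intensity gave 0.808 (proteasome, histones), and pairs without artefact spots 0.958 (heat shock). Leaving out a replicate number or a pair gave 0.215 to 0.991 (heat shock), 0.403 to 0.963 (epithelial junctions), 0.319 to 0.977 (glycolysis), 0.0020 to 0.997 (sterol synthesis), 0.577 to 0.965 (lipid, histones), 0.746 to 0.977 (chromatin), 0.319 to 0.965 (proteasome) and 0.652 to 0.977 (sperm). Sterol synthesis was called without replicate 1 (0.0125), without replicate 2 (0.0354) and without the pair on the second slide areas 1 and 2 (0.0020), all at the preset correlation; with an estimated one and all arrays its adjusted p was 0.867 by replicate numbers and 0.934 over pairs. Immediate early genes were called without replicate 4 (0.0371) and without the second slide areas 3 and 4 (0.0228), against 0.867 and 0.908 with an estimated correlation and all arrays. Endoplasmic reticulum stress genes were called in 10 of 33 settings, with adjusted p from 0.013 to 0.850 over all of them, among these without replicate 3 (0.0210), without replicate 4 (0.0336) and without the first slide areas 3 and 4 (0.0458), against 0.747 and 0.850 with an estimated correlation and all arrays.

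Of single genes, LUM was at 0.30 on the first slide alone, and CIRBP at -0.0099, FADS2 at -0.21 and IRF1 at 0.13 on the second. IRF1 was at 0.072 with the deposited values, by replicate numbers and over pairs, at 0.034 with median spot intensity, and between -0.13 and 0.010 with a replicate number or pair left out. The residual correlation of neighbouring areas was -0.651 with median centring and -0.808 without background correction. The dye term was called for 5742 probes without background correction, 10261 with the replicate number as a block, and, with a replicate number left out, 392 without replicate 4 and 0 without any other. Each replicate number left out leaves 1 orientation with 1 average, which is assumed to vary like the others. Above background in all channels were 11329 of 43794 probes; on the second slide area 1, where outlying negative control spots raised the limit, 26.3% were above it in Cy3 and 29.6% in Cy5, so that setting rests on this array.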

Other observations

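Adjusted over the endoplasmic reticulum stress list alone, 6 members passed over dye-swap pairs. Beside the 4 named in the report these were HERPUD1 at 0.36 ± 0.21 and DNAJC3 at 0.35 ± 0.18 (SD, n = 4 dye-swap pairs), both picked after their values were seen. None passed over all probes. TXNIP, which binds thioredoxin and was also picked after its value was seen, was at -0.88 ± 0.51.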
